A study of Zea mays with 6 samples.

How the data were processed

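Small RNA libraries from maize embryos were available for water, ABA and GA at 48 h, with 2 replicates each, grouped by the treatment label. The authors deposited for each library a table of predicted miRNA hairpins with the count of reads per mature arm and per precursor, the sequences, positions and folding energy. RNA was isolated with TRIzol, enriched for small RNAs with polyethylene glycol and size-selected on a gel between adapter ligations, per the labels' protocols. The tools named are cutadapt 1.2.1 and Bowtie 0.12.8, per the submitters' processing notes, which give no roles. The genome build, hairpin caller and annotation are not given in the sources used here, so positions are as the deposited tables give them and arms were not assigned to genes. The smallest precursor count in every deposited table was 5, so an arm that a table does not list may have had reads.

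The identifiers in the tables are serial numbers of each library, so the planned feature, the miRNA name, was replaced. Arms overlapping by at least 12 nt on a strand were joined into loci, and loci whose mature sequences were identical over at least 17 nt with a shift of at most 4 nt into 1 arm. The tables count reads that map to several loci whole at each, so each arm took the count of 1 locus, the one listed in all 6 libraries with the highest total; positions are those of that locus, and the sequence is the most counted one of the arm. This gave 2334 arms, 295 listed in every library and 285 after edgeR's filterByExpr. The choice of locus was made after a first version, which took the highest locus of each library, had been run; that version is kept as an alternative. Families came from a match to conserved mature sequences with at most 2 mismatches over at least 18 nt and a shift of at most 3 nt, with the reference sequences entered by hand after the data were opened. A guide arm (g) matched directly, a passenger arm (p) is the other arm of its precursor, tR marks a tRNA A-box motif and hp any other arm. Arms of near-identical family members share reads and cannot be split safely.

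Counts were tested with edgeR 4.0.16 (TMM factors, quasi-likelihood F test, all 6 libraries in 1 fit, group only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error was taken from the fold change and the F statistic. The common biological coefficient of variation was 0.293 with 3 residual degrees of freedom. Family counts were sums over arms, tested beside the unmatched arms and adjusted over the 21 families. Of the 9 lists, the 8 with a tested arm were tested with fry and camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison; fry asks whether a set's arms move one way on balance and does not compare it with other arms. CPM values are scaled by TMM. Samples, tests, lists, alternatives and the rule for named arms were fixed before the data were examined. That rule takes, per comparison, up to 10 arms in each direction past the threshold with at least 10 CPM in a group and no overlap between groups, filled up to 20 with the smallest unadjusted p. Of these 20, the conserved arms and the first 4 others are written out. The rule adds the 10 most abundant families and, for each list, the most abundant member (given at the family level) and any family past the threshold.

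Alternatives were DESeq2 1.42.0, RLE factors, library totals, other filters, only the compared libraries, a replicate block, each library left out, miR319 left out, a 2-fold minimum, counts divided among loci and distinct sequences. Added after seeing the data were the highest locus of each library, unlisted arms counted as 0, arms without the tRNA-like motif, and fry under other scalings, and the simulated overlap of both responses and the overlap with a library left out were added after the overlap was seen. With 1 library left in a group, that library is assumed to vary like the other groups. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom of 191, 132 and 85.7 for water, ABA and GA), so none was counted as a duplicate. Between groups, replicate 1 libraries differed less than replicates of a group did (17.9 for water and ABA, 43.2 for water and GA, 35.5 for ABA and GA), while the values for replicate 2 libraries in the same order were 145, 250.0 and 340.0.

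The procedure was tested on simulated counts with the real means, library sizes and dispersions, with 20 of 285 arms changed at each fold in 20 draws. For ABA against water it recovered 24.2% of 2-fold, 85.0% of 4-fold and 97.2% of 8-fold changes. For GA against water it recovered 27.8%, 81.8% and 96.2%, and for ABA against GA 24.2%, 84.2% and 97.5%. False calls made up 3.28%, 4.97% and 4.96% of calls in the 3 comparisons. A 2-fold change of a single arm was therefore mostly not detectable at this replication. Each draw held the 2-fold, 4-fold and 8-fold changes together, and no simulated library stood apart as water replicate 2 did. Recovery may be lower, and the share of false calls higher, with fewer changed arms or with such a library.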

Results

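Small RNAs from maize embryos were profiled after 48 h in water, abscisic acid (ABA) or gibberellin (GA), hormones with opposing roles in seed germination. Each treatment had 2 libraries, 6 in all. The deposited tables list predicted hairpin arms with their counts. After arms were joined across libraries, 285 arms listed in every library were tested, of which 61 belonged to 21 conserved miRNA families, 4 carried a tRNA-like motif and 220 matched no conserved family. The tested arms held 821464 and 409552 counts in water replicates 1 and 2, 683421 and 649697 in the ABA replicates, and 967142 and 854573 in the GA replicates. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

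Among the predicted hairpin arms listed in every library, few families dominated. Shares of families were taken over these 295 arms, and shares by length or motif over the 285 tested arms. Small RNAs outside predicted hairpins, and arms not listed in every library such as miR169-g2, are left out of them. miR319, which targets TCP transcription factors, held 37.8% ± 2.52 of the counts (SD, n = 6). miR159, which targets GAMYB-like factors, held 14.0% ± 5.36, miR168, which targets AGO1, held 12.9% ± 2.75, miR166, which targets HD-ZIP III factors, held 12.1% ± 2.56, and miR169, which targets NF-YA subunits, held 7.73% ± 1.52. These 5 families together held 84.6% ± 4.36. miR396 (2.12% ± 0.69), miR393 (1.67% ± 0.56), miR167 (1.48% ± 0.76), miR156 (0.977% ± 0.26) and miR171 (0.609% ± 0.22) completed the 10 most abundant families. Arms of 21 nt held 88.6% (95% Wilson interval 88.5% to 88.7%) of the counts in water replicate 2 and 95.4% (95% Wilson interval 95.3% to 95.4%) in GA replicate 1, the lowest and highest of the 6 libraries. Arms with the tRNA-like motif held 5.96% (95% Wilson interval 5.89% to 6.03%) in water replicate 2, and from 2.18% to 3.32% in the other 5 libraries. Intervals cover counting error only. Water replicate 2 had a median correlation of 0.947 with the other libraries across arms, while the lowest correlation between any 2 of the others was 0.958. With 2 libraries against 2, no exact permutation test of these shares can reach 0.05.

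**Figure D1:**
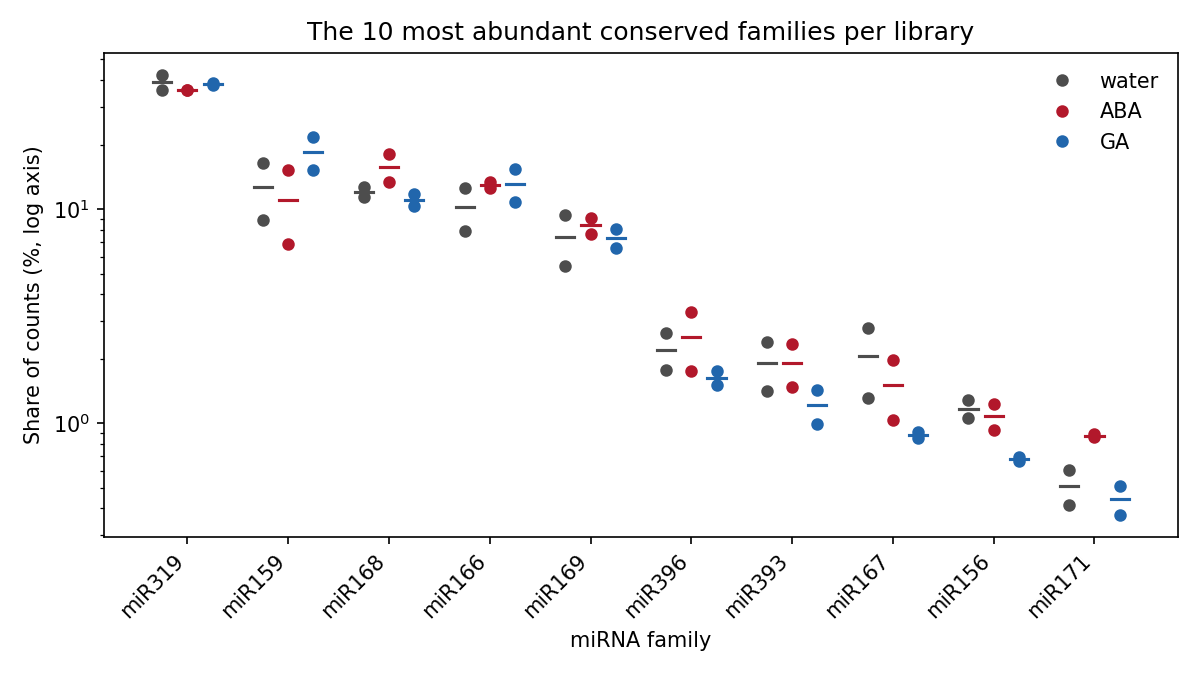
Share of the counts of arms listed in every library (percent, log axis) held by the 10 most abundant conserved families. Points are single libraries and bars are group means (n = 2 per group). miR319 held the highest share in every library, with a mean of 39.1% in water, 36.0% in ABA and 38.4% in GA.

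ABA was compared with water to find miRNAs that respond to ABA during germination. The strongest difference was in hp45, a hairpin arm outside the conserved families (GCGATGATGGCCGCGCGGGTTC; chromosome 10, minus strand, 2656170 to 2656191), at 107.0 ± 38.0 CPM in ABA and 427 ± 166 in water (SD, n = 2), a ratio of 0.251 (SE 0.43 on the log2 scale, edgeR adjusted p = 0.0537). The guide arm miR171-g1, of a family that targets GRAS factors, stood at 5759 ± 1479 CPM in ABA and 2788 ± 1739 in water (log2 fold change 1.05, SE 0.42). The guide arm miR167-g2, of a family that targets auxin response factors, stood at 4100 ± 1403 and 10638 ± 9518 (-1.37, SE 0.49). Neither miR171-g1 nor miR167-g2 reached the threshold. The other tested guide arm of the miR167 family, miR167-g1, stood at 9116 ± 2813 and 6890 ± 3137 (0.40, SE 0.38). The miR167 family as a whole had -0.42 (SE 0.35). No arm of the 285 passed with edgeR's quasi-likelihood test, 18 had an unadjusted p under 0.05 against 14.25 by chance, and DESeq2 called 1 arm, hp45, with 15 under 0.05. Among the 20 arms with the smallest p, none past the threshold, 15 were lower and 5 higher in ABA, and 7 were conserved. The laccase-targeting miR397-g1 had a log2 fold change of -0.95 (SE 0.46) and the SPL-targeting miR529-g1 had -0.92 (SE 0.44). The passenger arms miR166-p2, miR166-p3 and miR156-p3 had -1.61 (SE 0.45), -1.05 (SE 0.49) and -1.09 (SE 0.46). The unmatched arms hp127, hp24 and hp52 had -1.81, -1.72 and -1.49. Both libraries of a group lay on the same side of both of the other in 30.9% of arms, where chance gives 33.3%.

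Among families, miR529 and miR397 had log2 fold changes of -0.88 (SE 0.38) and -0.89 (SE 0.40) for ABA against water, miR408, which targets copper proteins, had -0.76 (SE 0.36), and miR171 had 0.74 (SE 0.35), each with edgeR adjusted p = 0.228. With edgeR 0 of 21 families passed and these 4 had an unadjusted p under 0.05, while DESeq2 called 0 with 1 under 0.05. The phase-change list held the guide arms miR156-g1 (0.17, SE 0.34) and miR529-g1 (-0.92, SE 0.44) and otherwise passenger arms of both families. In this list, 10 of 12 tested arms had negative values, with a median of -0.51, and the list did not pass by fry (adjusted p = 0.359). Its camera call (adjusted p = 0.0339 with a preset correlation) was lost at adjusted p = 0.683 with an estimated correlation. In the meristem and growth list (miR166, miR171, miR394, miR396), 0 of 16 arms passed over all arms and 1, miR166-p2, passed adjusted over the list alone (adjusted p = 0.0345). Water replicate 2 weighed on these values: 27 arms and 5 families passed without water replicate 1, and 1 arm (hp45) and 0 families without water replicate 2. Without that library miR167-g2 stood at 0.087, miR397-g1 at 0.29, hp52 at 0.36, hp24 at -0.17, hp127 at -0.51, miR156-p3 at -0.21, miR529-g1 at -0.38 and miR171-g1 at 0.53, and the miR397, miR408 and miR171 families at 0.21, -0.05 and 0.36; without water replicate 1 these families stood at -1.47, -1.19 and 1.30.

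GA was compared with water to find miRNAs that respond to GA. The arm with the smallest p was hp47, outside the conserved families (CATGCTAACACTGAACATTTTAG; chromosome 1, minus strand, 221740413 to 221740435), at 97.0 ± 6.79 CPM in GA and 445 ± 368 in water (SD, n = 2; log2 fold change -2.19, SE 0.54, edgeR adjusted p = 0.185). The passenger arm miR156-p3 stood at 123 ± 4.25 CPM in GA and 411 ± 262 in water (-1.73, SE 0.47), and miR167-g2 at 3219 ± 45.7 and 10638 ± 9518 (-1.72, SE 0.49). The other tested guide arm of miR167, miR167-g1, had 0.12 (SE 0.38). The guide arm miR396-g2, of the family that targets growth-regulating factors, stood at 6275 ± 1183 and 3167 ± 2458 (0.99, SE 0.44). The more abundant guide arm miR396-g1 stood at 13546 ± 445 and 15834 ± 4587 (-0.23, SE 0.37). The miR396 family as a whole had 0.03 (SE 0.34). No arm of the 285 passed with edgeR, 26 had an unadjusted p under 0.05 against 14.25 by chance, and DESeq2 called 1 arm, hp47, with 17 under 0.05. Among the 20 arms with the smallest p, 14 were lower and 6 higher in GA, and 5 were conserved. The passenger arms miR156-p4 and miR156-p2 had log2 fold changes of -1.22 (SE 0.42) and -0.90 (SE 0.34). The unmatched arms hp3, hp165 and hp52 had 1.24 (SE 0.37), -1.98 (SE 0.59) and -1.77 (SE 0.57). Groups lay apart without overlap in 31.9% of arms, where chance gives 33.3%. Without water replicate 2 the values were -0.90 for hp47, -0.85 for miR156-p3, -0.25 for miR167-g2, 0.40 for miR396-g2, -0.65 for miR156-p4, -0.79 for hp165 and 0.11 for hp52.

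Among families, miR159 had a log2 fold change of 0.94 (SE 0.41) for GA against water, miR166 had 0.75 (SE 0.36) and miR167 had -0.73 (SE 0.35), each with edgeR adjusted p = 0.270. With edgeR 0 of 21 families passed and these 3 had an unadjusted p under 0.05, while DESeq2 called 0 with 0 under 0.05. The phase-change list held the guide arms miR156-g1 (-0.14, SE 0.34) and miR529-g1 (-0.40, SE 0.43) and otherwise passenger arms. All 12 tested phase-change arms had negative values, with a median of -0.62, and the list did not pass by fry (adjusted p = 0.196). Its camera call (adjusted p = 0.000197 with a preset correlation) was lost at adjusted p = 0.372 with an estimated correlation. All 6 tested arms of miR159 and miR319, guide and passenger arms together, had positive values, with a median of 0.46 and a fry adjusted p of 0.132. Scaled by library totals, which moved the median of all arms to -0.46, 2 of 6 were positive and the list's mean lay 0.47 above that median. Adjusted over the list alone, 1 phase-change arm (miR156-p3, adjusted p = 0.0207) and 1 auxin arm (miR167-g2, adjusted p = 0.0226) passed, against 0 over all arms. Library totals gave 5 arms past the threshold, all lower in GA. Without water replicate 1, 32 arms and 5 families passed, without water replicate 2 0 arms and 0 families did, and without ABA replicate 1 or 2 1 arm, hp47, did. The miR159, miR166 and miR167 families stood at 0.45, 0.33 and -0.31 without water replicate 2 and at 1.68, 1.36 and -1.04 without water replicate 1.

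The direct comparison of ABA with GA tested the difference between the hormones. Arms of miR159, which targets GAMYB-like factors that act in GA signalling, and of miR319 were lower in ABA than in GA as a set by fry, and all 6 tested arms had negative values, with a mean log2 fold change of -0.68 and a median of -0.60 (fry adjusted p = 0.0487). The camera adjusted p was 0.0186 with a preset correlation, and this call was lost at adjusted p = 0.411 with an estimated correlation. Apart from miR159-g1 and miR319-g1, the tested arms were passenger arms (miR159-p1, miR159-p2, miR319-p1 and miR319-p2), so the 6 arms stand for 2 families. miR159-p2 and miR319-p2 stood at 16.0 and 15.7 CPM in ABA and at 24.4 and 24.3 in GA. miR159-g1 (TTTGGATTGAAGGGAGCTCTG) stood at 103706 ± 66494 CPM in ABA and 229715 ± 71592 in GA (-1.15, SE 0.48; SD, n = 2), and miR319-g1 (TTGGACTGAAGGGTGCTCCCT) at 327864 ± 44729 and 474467 ± 43557 (-0.53, SE 0.37). Of the 6 arms 0 passed, over all arms or adjusted over the list alone. In the replicate 1 libraries the miR159 family stood at 145517 CPM in ABA and 178717 in GA (15.1% and 15.3% of counts). In the replicate 2 libraries the family stood at 58168 and 278234 (6.87% and 21.6%), so its difference lay mainly there. Settings that ended the list's fry call included RLE factors (adjusted p = 0.148), miR319 left out (0.166), families as members (0.752), library totals (0.389, where the median of all arms lay at 0.45 and the list's mean 0.68 below it), and leaving out water replicate 1 (0.170), water replicate 2 (0.168), GA replicate 1 (0.391) or GA replicate 2 (0.328); over all alternatives its adjusted p ran from 0.00639 to 0.752.

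**Figure D2:**
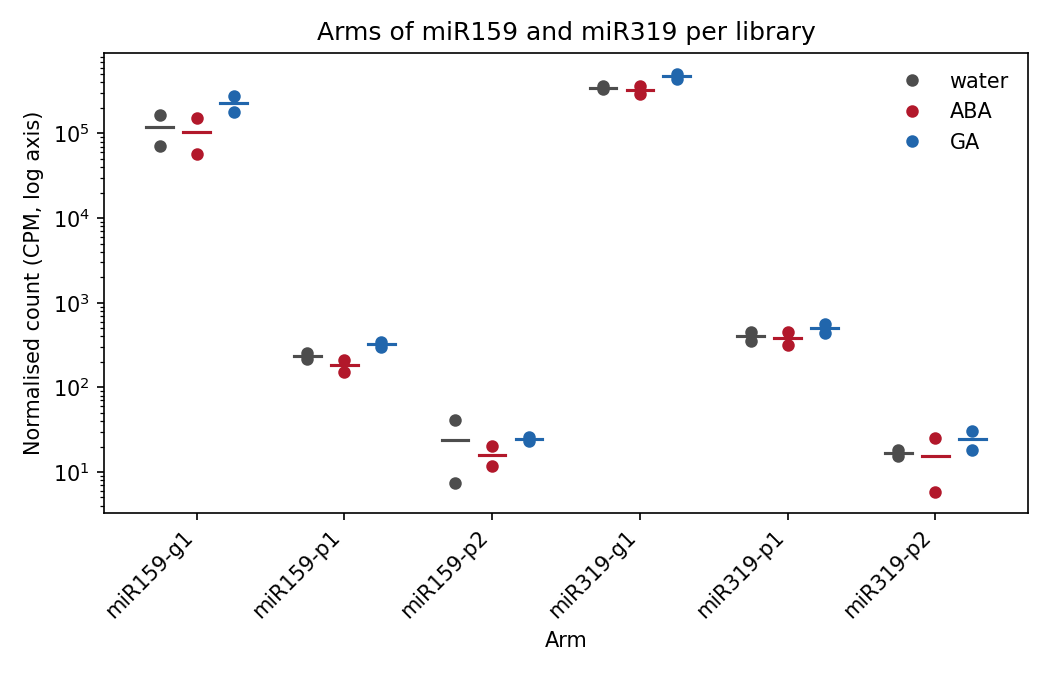
Normalised counts (CPM, log axis) of the 6 tested arms of miR159 and miR319; points are single libraries and bars are group means (n = 2 per group). The mean of miR159-g1 was 103706 in ABA and 229715 in GA, with the ABA libraries at 150725 and 56688 and the GA libraries at 179092 and 280338.

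Among single arms, hp143 (ATGGGCTTCGGTTGATCTGCTG; chromosome 5, minus strand, 125023726 to 125023747) stood at 33.4 ± 2.20 CPM in ABA and 105 ± 8.09 in GA (log2 fold change -1.65, SE 0.45, edgeR adjusted p = 0.412), and the passenger arm miR156-p8 at 95.5 ± 5.20 and 36.1 ± 13.4 (1.41, SE 0.47). The unmatched arms hp278, hp373 and hp479 had log2 fold changes of -1.77 (SE 0.55), 1.69 (SE 0.54) and 1.60 (SE 0.52). miR166-p2 had -1.25 (SE 0.45), miR396-p2 had 1.24 (SE 0.55) and miR171-g2 had 0.74 (SE 0.33). No arm of the 285 passed with edgeR, 23 had an unadjusted p under 0.05, and DESeq2 called 0 with 14 under 0.05. Groups lay apart without overlap in 46.7% of arms, where chance gives 33.3%. All arms come from the same 4 libraries and are not independent, so this share is a description and was not tested. The miR159 family had -1.17 (SE 0.41, edgeR adjusted p = 0.150); 0 of 21 families passed, this 1 had an unadjusted p under 0.05, and DESeq2 called 0 with 1 under 0.05. Fitted on the 4 ABA and GA libraries alone, or without either water replicate, 5 arms (hp143, hp278, hp79, miR156-p8 and miR166-p2) and the miR159 family passed; the family also passed without ABA replicate 1, and its adjusted p ran from 0.00334 there to 0.987 without GA replicate 2. The main fit estimated the spread of an arm from all 6 libraries, so the water pair weighed on this comparison too. Fits on the 4 libraries alone, or without a water replicate, held no spread between water libraries. Filter and TMM factors were also recomputed in those fits, and the part each played was not tested. Without ABA replicate 1 and without ABA replicate 2, the miR159 family stood at -1.99 and -0.61, miR159-g1 at -2.02 and -0.61, and miR166-p2 at -1.93 and -0.79.

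The other fixed lists passed by fry in 0 of the 3 comparisons, with 0 arms past the threshold over all arms. The auxin list (miR160, miR164, miR167, miR393; 9 arms) had medians of 0.30, 0.19 and 0.17 for ABA against water, GA against water and ABA against GA, though its mean for GA against water was -0.02. Its most abundant family, miR393, which targets auxin receptors, had family log2 fold changes of 0.0089, -0.19 and 0.20. The meristem and growth list had medians of 0.20, 0.02 and 0.08, the miR169 list (4 arms) 0.15, 0.04 and 0.17, and the nutrient list (miR395, miR827; 3 arms) 0.53, 0.20 and 0.33. The copper list (miR397, miR398, miR408, miR528; 7 arms) had -0.26, -0.50 and -0.18, and the small RNA machinery list (miR162, miR168; 4 arms) 0.31, 0.21 and 0.06. Of the reproductive list, a marker of anther tissue, miR2118 was listed with at most 6 counts and was not tested, and miR2275 and miR482 matched no listed arm. miR172, miR390 and miR399 were not listed in every library. For the phase-change list the median for ABA against GA was 0.41, with miR156, its most abundant family, at -0.12, -0.33 and 0.20. The most abundant families of the remaining lists were miR166 (0.30, 0.75 and -0.44), miR169 (0.13, 0.37 and -0.24), miR827 (0.52, 0.13 and 0.39), miR528 (-0.29, 0.20 and -0.50) and miR168 (0.37, 0.32 and 0.06), in the same order of comparisons. The miR159 and miR319 list had a median of -0.14 for ABA against water.

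The responses to ABA and GA were compared across the 285 arms, which are not independent replicates. Their log2 fold changes against water had a Pearson r of 0.45 and a Spearman rho of 0.36, while unchanged groups simulated against shared water libraries gave a mean r of 0.50 (SD 0.04, 100 draws) and a mean rho of 0.48 (SD 0.05). The log2 fold changes had the same sign in 60% of arms, against a simulated 66.7% ± 2.82. All of r, rho and this share lay below the simulated means but within the range of the draws. The lowest draws were 0.357 for rho and 59.7% for the share, so both lay at the edge of that range. The covariance was 0.14 against a simulated 0.13 ± 0.02, a difference under 1 simulated SD. Of the arms with an unadjusted p under 0.05, 7 were lower under both hormones (hp24, hp45, hp47, hp52, miR156-p3, miR167-g2 and tR4) against 0.84 for independent lists and a simulated 1.06 ± 1.01 with shared water libraries (at most 4 in 100 draws). None were higher under both, against 0.13 and a simulated 1.61 ± 1.41. The simulation drew all libraries of an arm from 1 mean and 1 dispersion, with no library standing apart as water replicate 2 did. It therefore cannot tell a shared response from the effect of that library. Without water replicate 2, 4 arms were lower under both, of which 1 (hp45) was among the 7, and 1 was higher under both. In that fit the 7, in the order named, stood at -0.17, -2.32, 0.19, 0.36, -0.21, 0.087 and -0.24 for ABA against water and at 0.11, -1.54, -0.90, 0.11, -0.85, -0.25 and -0.20 for GA against water. Without water replicate 1, 27 were lower and 13 higher under both, and 3 were lower without ABA replicate 1 and 4 without GA replicate 1. Without water replicate 1, r was 0.75, rho 0.70 and the covariance 0.55, and without ABA replicate 1 they were 0.25, 0.18 and 0.094. With 1 water library for each hormone, r was -0.18 or -0.14, depending on which library went with which hormone.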

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

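The tests of loci sharing a sequence, of a hormone library under the water label and of RNA fragments were chosen, or had their bounds revised, after the result was seen. As a signal in data that the comparisons do not use, 2 arms outside the comparisons were listed in both GA libraries and in no water library. hp5 (TGCCAGTGATGATTTGTCTGCAA; chromosome 10, plus strand, 144316027 to 144316049) had 3337 and 3196 counts, and hp14 (GAGGATTACTCTAATGAGCTGC; chromosome 9, plus strand, 78541072 to 78541093) had 1915 and 1681. Neither was listed in ABA. Loss from a table did occur, since 2 of 368 loci that shared the exact sequence of a locus with at least 1000 counts were unlisted in the same library (0.543%). Of 44 arms with at least 1000 counts in some library, 9 were listed in 1 library of a group and not in the other. In 8 of them the library that listed the arm had at least 1000 counts. For these arms, loss from a table and a difference between the libraries cannot be told apart. By the bound first written, a share of unlisted loci under 1% would have counted against loss from the tables. That bound was changed because loss, though rare, had occurred. To account for these 2 arms, loss would have to recur in every water and ABA table. hp5 had 1 locus, so the rate among loci sharing a sequence does not cover it. Among 33 arms with at least 100 counts listed in exactly 2 or 4 libraries, 21.2% followed a treatment group (20% by chance, one-sided exact binomial p = 0.500), so loss in the tables and a GA response cannot be told apart, since an unlisted arm has no count.

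Water replicate 2 stood apart from the other libraries by correlation. By chi-square per degree of freedom, ABA replicate 2 lay as far from the others (132 to 340) as water replicate 2 did (145 to 253). Pairs without either library had 17.9 to 85.7. The explanations below were weighed for water replicate 2 alone. Lower depth was argued against, since water replicate 1 thinned to its depth kept a median correlation of at least 0.970 with the hormone libraries, against 0.946 for water replicate 2 itself. RNA fragments other than miRNAs as the whole source were argued against by the conserved arms alone, where its median correlation was 0.965 and the lowest between other libraries 0.980; the first version did not also require its highest, 0.967, to stay below, and came out the same way. A hormone library carrying the water label stays open: its highest correlation with a hormone library, 0.949, lay 0.000657 above its correlation with water replicate 1, and a library apart from all others does not show which label it should carry; bounds written earlier would have counted against it and were dropped for that reason. A difference between the embryos themselves, or in the handling of that library, stays open and was not tested.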

How the results depend on the processing

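The highest locus of each library, unlisted arms as 0, arms without the tRNA-like motif, fry under other scalings, and the overlap of both responses with a library left out were chosen after the data were seen. The single-arm counts of 0 rose in several settings. For ABA against water 1 arm, hp45, passed with DESeq2, RLE factors, no filter, the 10 CPM filter (which kept more arms than the main one), the replicate block, miR319 left out, counts divided among loci and without tRNA-motif arms; leaving out a library gave 0 to 27. For GA against water 1 passed with DESeq2, 5 with library totals and 3 with the replicate block, and leaving out a library gave 0 to 32. For ABA against GA 5 passed with only the 4 samples compared and 1 (hp161) with the highest locus of each library, where the locus counted can differ between libraries; leaving out a library gave 0 to 5. Both extremes against water came without water replicate 1, which leaves water replicate 2 as the lone control.

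Families passing ranged from 0 to 5 for ABA against water, 0 to 5 for GA against water and 0 to 1 for ABA against GA when a library was left out; for the last, 1 (miR159) also passed with only the 4 samples compared and 1 with the replicate block. The list count of 1 became 3 with the preset camera correlation, 0 with the estimated correlation, 0 with the replicate block, 0 with families as members, 0 with RLE factors, 3 with library totals and 0 with miR319 left out; leaving out a library gave 0 to 2. The miR159 and miR319 mean of -0.68 lost its call at -0.68 (estimated correlation), -0.75 (replicate block), -0.85 (families as members), -0.65 (RLE), -0.23 (library totals) and -0.86 (miR319 left out), and ranged from -0.97 to -0.61 with a library left out. The replicate block used a number that 2 pairs cannot show to be more than a label: same-numbered deviations correlated at 0.11, 0.09 and 0.02 between groups.

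The correlation of both responses, 0.45, moved to -0.18 and -0.14 when each hormone had its own water library, and ranged from 0.25 to 0.75 with a library left out. The 7 arms lower and 0 higher under both hormones became 3 to 27 and 0 to 13 with a library left out. The share of the 5 leading families moved to 78.5% with miR319 left out and 91.2% with counts taken at every locus. Without water replicate 2 the sign turned in 5 cases among the arms written out for a comparison and the families with an unadjusted p under 0.05. Other named arms were not tallied. Of these, hp47 moved from -1.09 to 0.19 for ABA against water and hp24 from -1.43 to 0.11 for GA against water. For ABA against water, leaving out a library gave -2.16 to 0.087 for miR167-g2, -1.68 to 0.29 for miR397-g1, -2.36 to 0.36 for hp52 and -1.47 to 0.21 for the miR397 family; for GA against water it gave -2.62 to 0.11 for hp52. Of the other values of the arms written out and of those families, 599 kept their direction and side of the threshold and 62 came past it. The cause of these changes was not tested.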

Other observations

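The test in this part had its bound changed after its value was seen. Passenger arms of miR156, the family that targets SPL factors, formed a group that was not fixed in advance. All 9 tested passenger arms had negative log2 fold changes for GA against water, with a median of -0.83 and a range from -1.73 to -0.11, and 8 of 9 had negative values for ABA against water, with a median of -0.42. The guide arm miR156-g1 had -0.14 (SE 0.34) for GA against water. Water replicate 2 as the only source stays open: without it the median was -0.57, which the bound of -0.3 first written would have counted against it, but the set, picked for its pattern, did not pass fry at 0.05 in that fit. A lower level of miR156 passenger arms in GA may be a hypothesis for further libraries.

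Abundant conserved arms were missing from some tables. miR169-g2 (CAGCCAAGGATGACTTGCCGA) had 2719 and 3754 counts in water and 3365 and 3629 in ABA and was listed in neither GA library. miR166-g3 (TCGGACCAGGCTTCATTCCTC) had 792 counts in water replicate 2, 1852 in ABA replicate 2 and 2225 in GA replicate 1 and was not listed in the others.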
